A study of Homo sapiens with 4 samples.

How the data were processed

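RNA bound by YBX1 was measured by RNA immunoprecipitation and sequencing in PANC-1 cells, an established human pancreatic cancer line. Per the labels, all cells had been pretreated with vesicles derived from CAFs, an abbreviation used in this field for cancer-associated fibroblasts. The 4 samples form 2 groups of 2: YBX1 immunoprecipitates (IP) and inputs, each with replicates 1 and 2. Per the labels' protocols, cells were crosslinked with ultraviolet light, lysed, sonicated and treated with RNase I and DNase before YBX1 was captured on beads, and libraries were made with a DNA library kit. No sample without vesicles and no control antibody was analysed here, so the lists describe RNA recovered with YBX1 over input in treated cells. The labels do not say whether the replicates came from separate cultures, so agreement between them may reflect technical repeats.

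The deposited data were 2 annotated peak lists. Each list compared 1 IP library with the input of the same replicate number, and the replicates were not pooled. Per the submitters' processing notes, reads were trimmed with cutadapt 1.9.1 and aligned with Bowtie2 2.2.4, and the genome build was hg19. The peak caller is not given in the sources used here. Each peak's tag count, per the file headers, is the number of reads inside the peak and is not scaled to library size. The deposited fold is an enrichment of IP over input, as the authors' caller scaled it, and the input reads behind it were not used here. The deposited significance score is 10 times the negative log10 of the caller's p. Each peak also carries an empirical false discovery rate in percent, per the file headers. A p threshold of 0.001 stands in the title of each sheet, while the smallest score was 119.51 in the replicate 1 list and 30 in the replicate 2 list. Fold, p and false discovery rate are the authors' own values per peak and were used to describe, rank and filter peaks.

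Each list holds a row per peak and RefSeq transcript, with 60488 rows for replicate 1 and 55416 for replicate 2. Rows were collapsed to unique peaks. The deposited length equalled end minus start plus 1 in every peak, so positions are given as deposited, counted from 1, on hg19. The submitters' annotation gives each peak 1 class. By the deposited distances, promoter peaks lay within 2000 bp of a transcription start and upstream peaks between there and 20000 bp before it. Exon peaks lay 2025 bp or more after a start in replicate 1 and 2004 bp or more in replicate 2. The exon class thus leaves out exons nearer to the start. Genes were keyed to current symbols through unversioned RefSeq accessions, which matched 98.8% of replicate 1 rows and 98.9% of replicate 2 rows; a further 1.05% and 0.893% matched by symbol. The reference table was of assembly GRCh38, so it was used only for names, gene types, which genes neighbour each other and, in added tests, gene lengths. Symbols are printed as the lists give them.

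A peak was called shared when it overlapped a peak of the other list by 1 bp or more. Overlap was compared with 100 random placements of the replicate 2 peaks on the same chromosome and, for peaks wholly inside the gene they name, within the same gene (permutation, one-sided). A gene held a shared peak when shared peaks of both lists named it. Genes named in each list were compared by Fisher's exact test over 29989 RefSeq genes with a curated transcript. That table was not stratified in the main test, because hg19 lengths of genes outside the lists were not used here; an odds ratio pooled over 10 classes of GRCh38 gene length (Mantel-Haenszel) was added after the data were seen. Shared and unshared peaks were compared in each class by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over 10 tests. Peaks in the same gene are not independent, so these p-values are too small for a statement about genes.

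Gene lists were written before the data were examined. Of 27 lists, 26 had a member in the background; the list of mitochondrial transcripts had none and was not tested. The number of members with a shared peak was set against 10000 random lists of the same size (permutation, two-sided, Benjamini-Hochberg over 26 lists). The plan called for random lists matched on gene length. With no hg19 lengths the main test was unmatched, a departure from the plan, and the lists matched on GRCh38 length below come nearest to it. Lists matched in 10 classes of GRCh38 gene length over all genes, lists drawn from protein-coding genes, and lists matched in 10 classes of transcript span among genes named in either peak list were added after the data were seen. Exact hypergeometric p-values were computed beside the random lists. A planned analysis of sequence motifs was not run, since no genome of the build was used here.

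Genes named in the text follow a rule fixed before the data were examined. Genes were ranked by the smaller of the 2 replicates' highest folds among shared peaks. The rule takes the 12 highest, the 8 genes with the most shared peaks, the 8 highest protein-coding genes by exon peaks, the 3 highest of each gene list, and YBX1. Some genes that the rule takes are not reported here. A gene's highest peaks in the 2 lists can lie in different places. Alternatives covered stricter p and fold thresholds, chromosomes 1 to 22 and X, 50% overlap of both peaks and lists of equal length. Exon peaks only and each replicate list alone were also used. Added later were a score of 200 or more and genes whose transcript bounds hold the middle of the peak.

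Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The steps were tested on simulated data. For the overlap between replicates, with 27669 simulated peaks and 30% planted as shared, 31.0% were found. For the gene lists, with 29989 genes, all 260 lists of 30 genes planted at about 3 times the background share were called and 3 of 260 unplanted lists were. Every planted list held the same number of marked genes, and smaller excesses were not simulated, so the power to find those is not known. For the feature classes, a planted odds ratio of 1.6 over 27669 peaks was found as 1.62. Reads inside peaks came to 12243468 for replicate 1 and 3140931 for replicate 2; total library depths were not used here. Intervals are 95% and cover counting error only.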

Results

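YBX1 is a cold-shock domain protein that binds RNA and is known to affect messenger RNA stability and translation. The series asks which transcripts YBX1 binds in PANC-1 cells pretreated with CAF-derived vesicles. The replicate 1 list held 27669 peaks covering 19.8 Mb and the replicate 2 list 25492 peaks covering 16.0 Mb. The median peak held 45 reads in replicate 1 and 15 in replicate 2, and the smallest peaks held 11 and 6 reads; the lists also start at different scores, 119.51 and 30. The authors' median fold over input was 9.33 in replicate 1 and 25.31 in replicate 2. The authors' false discovery rate was high in both: its median was 18.3% in replicate 1, where 4 peaks were at 10% or less, and 100% in replicate 2, where 14262 peaks (55.9%) were at 100% and the lowest value was 28.1%. The comparisons therefore rest mainly on peaks found in both lists, while the overlap shares and the genes each list names use all peaks.

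YBX1's own transcript was among the shared genes. It held 4 peaks in each list, all shared, on chromosome 1 of hg19. The promoter peak lay at 43148037 to 43148588 in replicate 1 (fold 11.25, 1740 reads) and at 43147929 to 43148493 in replicate 2 (fold 26.98, 505 reads). The last exon peak began at 43167592 in both lists and had a fold of 34.15 with 7886 reads in replicate 1 and 15.69 with 1482 reads in replicate 2. The exon peaks between them had folds from 10.1 to 13.4 over the 2 lists.

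The first comparison asked whether the replicates marked the same places. Of the replicate 1 peaks, 31.6% overlapped a replicate 2 peak (8734 peaks; 95% Wilson interval 31.0% to 32.1%), and 34.7% of the replicate 2 peaks overlapped a replicate 1 peak (8845 peaks; 34.1% to 35.3%). With the replicate 2 peaks placed at random on the same chromosomes the replicate 1 share averaged 1.40%, and it was never above 1.59% in 100 placements (permutation p = 0.0099, one-sided, the smallest that 100 placements can give). Within genes the margin was smaller. Of the 15192 replicate 1 peaks inside the gene they name, 25.9% overlapped a replicate 2 peak that also lay inside its gene (15333 peaks). With those replicate 2 peaks placed at random within the same genes it was 5.29% (permutation p = 0.0099, one-sided). Places were drawn evenly over the whole gene, introns included. Peaks that gather in exons in both lists would therefore exceed random placement even without common binding sites, so the test cannot show such sites. The share rose to 80.3% in the 10% of replicate 1 peaks with the smallest p and to 80.5% in those of replicate 2, and was 16.0% and 27.6% in the 10% with the largest p. Shared peaks were longer, with medians of 649 and 634 bp against 289 and 286 bp for unshared peaks, and held more reads, with medians of 180 and 54 against 28 and 10. Their folds were lower, with medians of 7.69 and 17.4 against 10.05 and 25.31.

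**Figure D1:**
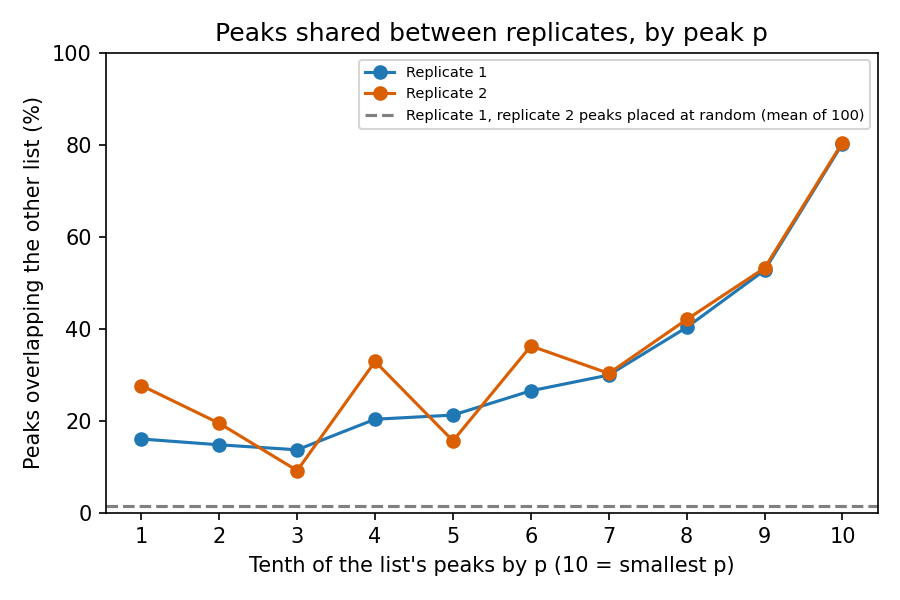
Percent of peaks that overlapped a peak of the other list (y axis), for 10 equal parts of a list's peaks ordered by the authors' p (x axis, 10 is the smallest p); each point is 1 part of 1 list, and the dashed line is the mean replicate 1 share over 100 random placements, 1.40%. The replicate 1 share is 16.0% in the part with the largest p and 80.3% in that with the smallest.

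The highest folds among shared peaks lay in genes of varied function. HOMER2, a scaffold protein of synapses and other signalling sites, ranked first with an exon peak on chromosome 15 at 83561345 to 83561658 in replicate 1 (fold 96.21, 134 reads), which overlapped a replicate 2 peak of fold 113.9 with 27 reads. DTNB, a dystrobrevin, followed with folds of 89.03 and 92.81 at different exon peaks. XYLT2, a xylosyltransferase of proteoglycan synthesis, had a promoter peak with folds of 79.7 and 88.59. The zinc finger gene ZNF410 had 68.93 and 88.59 at different exon peaks. PIP5K1C, a phosphoinositide kinase, had 54.26 and 84.37, also at different exon peaks. VEGFC, a growth factor for lymphatic vessels, had 53.85 and 67.5 in an exon, and FN1, which encodes fibronectin, had 49.54 and 80.15 in an exon. The other genes of the 12 were OR6S1 and CRIP2, whose highest peaks lay between or upstream of genes, the calcium channel ITPR3, the exportin XPO6, whose highest replicate 1 peak was intergenic, and EPB41L1, with replicate 1 folds from 48.11 to 59.19. FARP2 was added by the exon rule, with 47.89 and 67.27. In replicate 2 these peaks held from 12 reads at EPB41L1 and 16 at VEGFC to 63 at XPO6, so their folds are imprecise. The authors' false discovery rate of these replicate 2 peaks ran from 34.65% at CRIP2 to 100% at VEGFC and EPB41L1. Some replicate 2 peaks with equal reads had equal folds, 88.59 at 21 reads for XYLT2 and ZNF410. PIP5K1C and ITPR3 both had 84.37 at 20 reads. Input reads were not used here, so how far these folds reflect input is not known. At -log10 p of 5 or more the smaller fold of EPB41L1 was 21.14.

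The corepressor gene NCOR1 had the most shared peaks, 17 in each list. HDLBP, which encodes the RNA-binding protein vigilin, had 14 in replicate 1 and 13 in replicate 2. XPO6 and the Wnt co-receptor LRP5 had 11 each, and the receptor IGF1R and the transporter ABCC1 had 10 each in both lists. RNF213 had 9 in replicate 1 and 13 in replicate 2.

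Across the 8734 shared peaks of replicate 1 and their widest partners, Spearman's rho of the folds was 0.441 and Pearson's r of log2 fold was 0.408. The read counts of the same pairs ranked more alike, with a rho of 0.878. These coefficients are across peaks, which are not independent replicates. Fold values recur in steps, and not only among weak peaks. In replicate 2, 3383 peaks had a fold of exactly 25.31, with a median of 6 reads and a highest count of 327. In replicate 1, 1143 peaks had a fold of 7.9, with a median of 11 reads and a highest count of 4520. Some of the highest folds recur too, such as 88.59 in replicate 2 for XYLT2 and ZNF410.

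**Figure D2:**
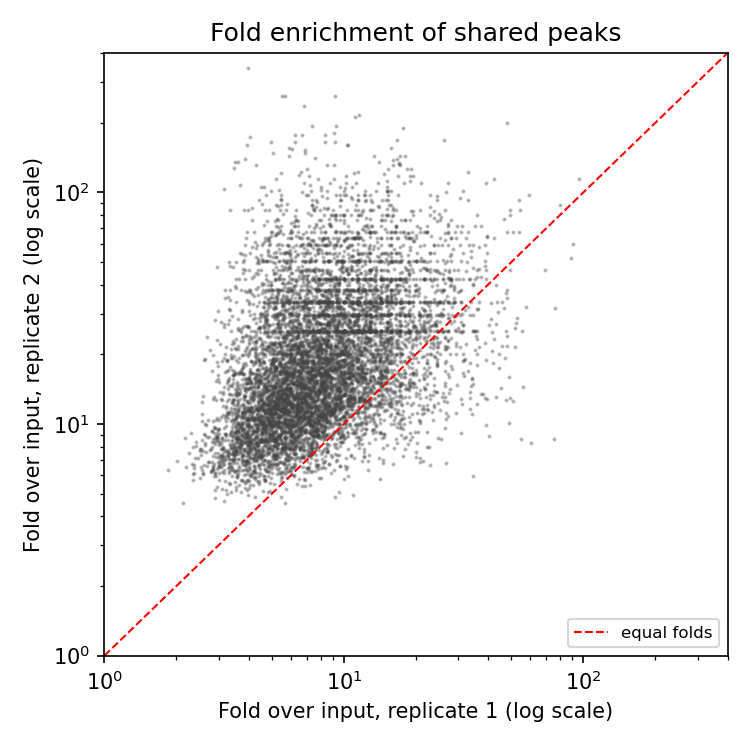
The authors' fold over input of each shared replicate 1 peak (x axis, log scale) and of its widest overlapping replicate 2 peak (y axis, log scale); each of the 8734 points is a pair of peaks and the dashed line marks equal folds. Horizontal bands are fold values that many replicate 2 peaks have in common, and Spearman's rho is 0.441.

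The second comparison asked whether the replicates named the same genes. Both lists named 7810 of 29989 RefSeq genes, replicate 1 alone 3589, replicate 2 alone 3003 and neither 15587, an odds ratio of 11.3 (95% interval 10.7 to 11.9; Fisher's exact p, two-sided, too small for the software to represent). Pooled over 10 classes of gene length it was 10.7. Neither odds ratio was adjusted for how strongly genes are transcribed, so the lists can agree because the same genes are transcribed. A stricter set, the genes with a shared peak, numbered 5066. Of these, 4174 were protein-coding, 403 were long non-coding RNA genes, 249 microRNA genes, 135 transcribed pseudogenes and 69 small nucleolar RNA genes. A shared exon peak was held by 1914 genes. Of the 5066 genes, 3274 (64.6%) also held the middle of a shared peak inside their transcript bounds in both lists. For the rest, another gene need not lie under the peak, since a middle can fall just before a start.

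The third comparison asked where shared peaks lay. Exons held the most, 40% of shared against 29.9% of unshared peaks in replicate 1 (odds ratio 1.57, adjusted p = 1.92e-61, Fisher's exact test) and 39.2% against 26.8% in replicate 2 (odds ratio 1.77, adjusted p = 8.93e-91). Introns went the other way, with 11.1% of shared against 20.6% of unshared peaks in replicate 1 (odds ratio 0.483, adjusted exact p = 2.18e-87) and 12.3% against 29.7% in replicate 2 (odds ratio 0.330, adjusted p = 1.61e-230). Exon peaks also held more reads than intron peaks, with medians of 59 against 22 in replicate 1 and 21 against 10 in replicate 2. Shared peaks held more reads than unshared ones, and the class tests were not adjusted for reads. Class and read count therefore cannot be told apart here. Upstream peaks were more frequent among shared peaks, with odds ratios of 1.17 and 1.38 (adjusted exact p = 4.69e-07 and 2.04e-22), and intergenic peaks less frequent, with 0.732 and 0.787 (adjusted exact p = 1.56e-14 and 6.70e-09). Promoter peaks were more frequent in replicate 2 (odds ratio 1.22, adjusted exact p = 2.11e-07), and in replicate 1 the odds ratio was 0.989 (adjusted p = 0.772). In replicate 2, at -log10 p of 5 or more, the promoter and intergenic odds ratios were 1.11 and 0.896 (adjusted exact p = 0.0538 and 0.0584). Some of these results turned or ended at a stricter score. Among peaks with a score of 200 or more in both lists, a threshold chosen after the data were seen, the odds ratio for exons was 0.791 in replicate 1 and 0.520 in replicate 2, and that for intergenic peaks was 1.46 and 1.5 (adjusted exact p = 4.96e-05 and 0.0717). In replicate 2 it was 0.937 for introns and 1.53 for promoters (adjusted exact p = 0.738 and 0.0607). Of upstream peaks, 73.7% in replicate 1 and 74.5% in replicate 2 lay inside the bounds of a listed gene.

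**Figure D3:**
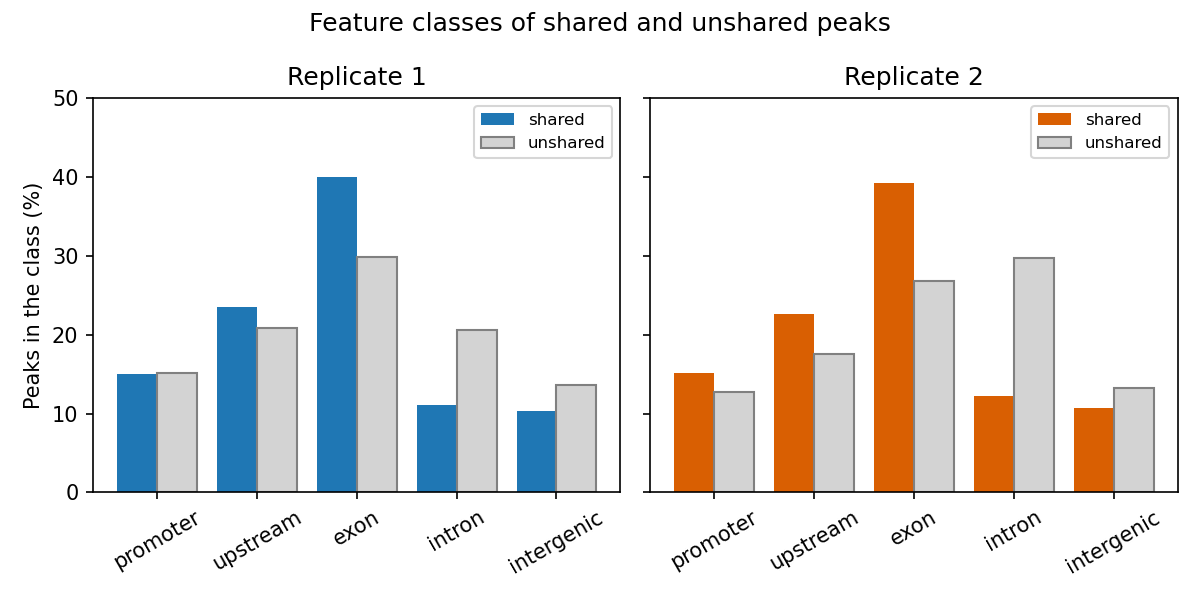
Percent of shared (coloured bars) and unshared (grey bars) peaks in each annotation class (x axis), for replicate 1 on the left and replicate 2 on the right. Exons held 40% of shared and 29.9% of unshared replicate 1 peaks, and introns 11.1% and 20.6%.

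The fourth comparison asked which gene groups held shared peaks. Over all genes the share was 16.8%, and over protein-coding genes 21.5%. Of 26 lists, 10 held more genes with a shared peak than random lists, 2 held fewer, and 14 did not pass. No random list was matched on how strongly genes are transcribed, so a list can stand apart because its genes are transcribed or silent. Whether YBX1 prefers any of these groups was not tested. Against random lists matched on gene length, added later, the same 10 were above. Abundant housekeeping genes stood highest, with 26 of 37 (70.3%, adjusted permutation p = 0.000743, the smallest that 10000 random lists gave here). They include the ferritin gene FTH1 with folds of 27.79 and 33.28, the glycolytic PKM with 24.27 and 26.79, and GAPDH with 21.75 and 25. The PKM and GAPDH peaks lie upstream of these genes, those of GAPDH at -17445 and -17467 bp from its start. Genes mutated in pancreatic cancer followed with 21 of 32 (65.6%, adjusted permutation p = 0.000743), among them the receptor TGFBR2 with 38.77 and 84.37 and the remodeller SMARCA4 with 21.54 and 23.81. Replication-dependent histone genes had 28 of 52 (53.8%, adjusted permutation p = 0.000743), such as HIST2H2AA3 with 19.41 and 25.9, HIST1H2AC with 13.47 and 27.25 and HIST1H2AI with 12.41 and 23.47. Histone genes lie in clusters, and a peak can name several. Counted by the transcript bounds that held the peak's middle in both lists, 11 of 52 had one (adjusted permutation p = 0.285). The middle can fall just before a start, at -7 and -82 bp for HIST2H2AA3, so this count does not place the peaks in other genes.

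Lists of translation and adhesion genes were also above random lists. Translation factors had 15 of 31 (adjusted permutation p = 0.000743), among them EEF1D with folds of 23.41 and 41.5, EIF4G3 with 14.2 and 63.28 (smaller fold 4.84 at -log10 p of 5 or more) and EIF4G1 with 14.19 and 21.88. Ribosomal protein genes had 29 of 78 (adjusted permutation p = 0.000743), led by RPS16 with 24.28 and 27.06, RPL13 with 16.79 and 30.0 and RPL12 with 15.9 and 29.53. The EEF1D and RPS16 peaks and the replicate 2 peak of RPL12 lie upstream of these genes, those of RPS16 at -17432 and -17588 bp. With exon peaks alone the ribosomal list fell to 0.404 of the random mean (adjusted permutation p = 0.397), and translation factors and glycolysis genes no longer passed (0.102 and 0.107). The exon class leaves out peaks within 2000 bp of a start, such as those of RPL13 at 590 and 731 bp. This setting therefore cannot judge short genes. Genes of epithelial to mesenchymal transition and adhesion had 17 of 36 (adjusted permutation p = 0.000743), with FN1, the cadherin CDH1 at 33.14 and 122.34 and the integrin ITGA2 at 24.41 and 33.46. Glycolysis genes had 11 of 25 (adjusted permutation p = 0.00982), with PFKL at 29.79 and 71.72 and, upstream of the gene, ALDOC at 36.13 and 23.6. Wnt signalling genes had 12 of 28 (adjusted permutation p = 0.00715), with WNT7B at 18.47 and 25.81, LRP5 at 15.49 and 40.83 and BCL9L at 13.81 and 21.76. At a score of 200 or more the adhesion, glycolysis and Wnt lists did not pass (adjusted permutation p = 0.0864, 0.0864 and 0.979).

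Lists tied to YBX1 itself were above random lists of all genes. Genes linked to YBX1 in the literature had 12 of 31 (adjusted permutation p = 0.0156), among them EGFR with 24.41 and 50 (smaller fold 6.59 at -log10 p of 5 or more), CHD3 with 22.16 and 71.72 and SMAD7 with 11.65 and 61.54, the last in intergenic peaks 81510 and 80032 bp from the SMAD7 start. The YBX1 family and its partners in messenger ribonucleoproteins had 10 of 25 (adjusted permutation p = 0.0269), among them IGF2BP2 with 45.58 and 21.76 and YBX3 with 16.4 and 51.12. Against protein-coding genes alone these lists did not pass, with adjusted permutation p of 0.0896 and 0.104, while counted by transcript bounds they had 14 of 31 and 11 of 25 (adjusted permutation p = 0.000520 and 0.00189). The literature list also did not pass with 50% overlap of both peaks (adjusted permutation p = 0.116), with exon peaks only (0.102) or at a score of 200 or more (0.979). The family list did not pass in the replicate 1 list alone, at 1.48 of the random mean (adjusted permutation p = 0.128), at a fold of 4 or more (0.0581), with exon peaks only (0.107) or at a score of 200 or more (0.0864). Among genes named in either list, which leaves out all genes without a peak, and matched on span, 3 of the 10 lists passed, those of housekeeping, pancreatic cancer and histone genes (adjusted permutation p = 0.00260, 0.00347 and 0.00260). Matched p for the other 7 ran from 0.0962 to 1.

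Olfactory receptor genes had 3 of 145 (2.07%, adjusted permutation p = 0.000743): OR6S1, OR2S2 and OR10K1, the last of these with folds of 2.31 and 9.18. Their peaks lay upstream of or between genes, and 0 of 145 held one within their bounds. Immune markers had 0 of 24 (adjusted permutation p = 0.0438), a call at the margin, since the exact hypergeometric p after adjustment was 0.0520 and the call ended at -log10 p of 5 or more (adjusted permutation p = 0.118), at a fold of 4 or more (0.0667) and by transcript bounds (0.285). Neuronal genes had 1 of 30, SYT1 (adjusted permutation p = 0.103). They passed as fewer against random lists matched on gene length (adjusted permutation p = 0.0328), against protein-coding genes (0.0372), at -log10 p of 5 or more (0.0479) and in the replicate 2 list alone (0.00709). Markers of fibroblasts, the cells that shed the vesicles, had 4 of 27 (adjusted permutation p = 1), with COL5A1 at 15.26 and 29.53, FBLN1 at 9.91 and 25.74 and TAGLN, upstream of the gene, at 9.12 and 25.31, where the replicate 2 peak held 6 reads. Endothelial markers had 1 of 14, ENG (adjusted permutation p = 0.632), and exocrine pancreas markers 2 of 24, CEL and CTRC, by upstream peaks (adjusted permutation p = 0.461). The exocrine list passed as fewer in each replicate list alone (adjusted permutation p = 0.0216 in replicate 1 and 0.0274 in replicate 2).

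The remaining lists did not pass the adjusted threshold when genes were counted as the annotation names them. Counted by the transcript bounds that hold the peak, 4 of them did: cell cycle with 16 of 37 and hypoxia and angiogenesis with 12 of 25 (adjusted permutation p = 0.000520 for each), splicing factors with 13 of 37 (adjusted permutation p = 0.00520) and drug response with 10 of 30 (adjusted permutation p = 0.0319). At -log10 p of 5 or more, drug response and vesicle biogenesis stood at 2.29 and 2.43 of the random mean (adjusted permutation p = 0.0479 for each). Cell cycle, splicing, drug response and ferroptosis genes passed in each replicate list alone, and those of hypoxia, vesicle biogenesis and N6-methyladenosine in the replicate 2 list alone. The writers, readers and erasers of 5-methylcytosine had 4 of 17 (adjusted permutation p = 0.655), with NSUN4 at 22.98 and 42.9 and DNMT1 at 26.57 and 21.07, and those of N6-methyladenosine 5 of 18 (adjusted permutation p = 0.434), with CBLL1, YTHDC2 and METTL3. Drug response genes had 9 of 30 (adjusted permutation p = 0.172), with the transporter ABCC3 at 42.36 and, upstream, 33.75 and the repair gene ERCC1 at 16.22 and 36.06. Ferroptosis genes had 8 of 29 (adjusted permutation p = 0.268), with NFE2L2 at 11.99 and 16.0 and GPX4 at 11.49 and 15.35. Cell cycle genes had 11 of 37 (adjusted permutation p = 0.134), with MCM7 at 20.07 and 65.34 in upstream peaks, MCM5 at 18.46 and 25.31 and MKI67 at 15.8 and 27.08. Hypoxia and angiogenesis genes had 8 of 25 (adjusted permutation p = 0.151), with VEGFC, EPAS1 and NRP1. Splicing factors had 10 of 37 (adjusted permutation p = 0.240), with TRA2A, SNRNP200 and SF3B1. Vesicle biogenesis genes had 8 of 25 (adjusted permutation p = 0.151), with RAB35 (upstream), RAB11A and VPS25. Nuclear long non-coding and 7S RNA genes had 3 of 28, MEG3, SNHG3 (upstream) and NORAD (adjusted permutation p = 0.632), and the list of vesicle small RNA genes and microRNA host genes 1 of 17, the long non-coding host gene MIRLET7BHG, with peaks in an intron and, in replicate 2, upstream (adjusted permutation p = 0.461).

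Folds of single genes depended on which peaks were kept. The folds printed for a gene are its highest in each list and can come from peaks that do not overlap, as for CRIP2, EPB41L1, TGFBR2, EGFR, LRP5, MCM5 and EIF4G3. The smaller of a gene's 2 folds went down to 6.23 for CRIP2, 21.15 for ITPR3, 5.27 for CHD3 and 6.71 for NSUN4 with exon peaks only, and to 12.11 for YBX1 and 11.56 for MCM7 with 50% overlap. At a score of 200 or more it was 15.44 for XPO6, 7.04 for TGFBR2, 5.64 for IGF2BP2, 5.58 for MKI67, 4.93 for WNT7B, 6.78 for EIF4G1 and 14.05 for GAPDH. By transcript bounds it was 8.63 for PKM and 14.73 for EEF1D.

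**Figure D4:**
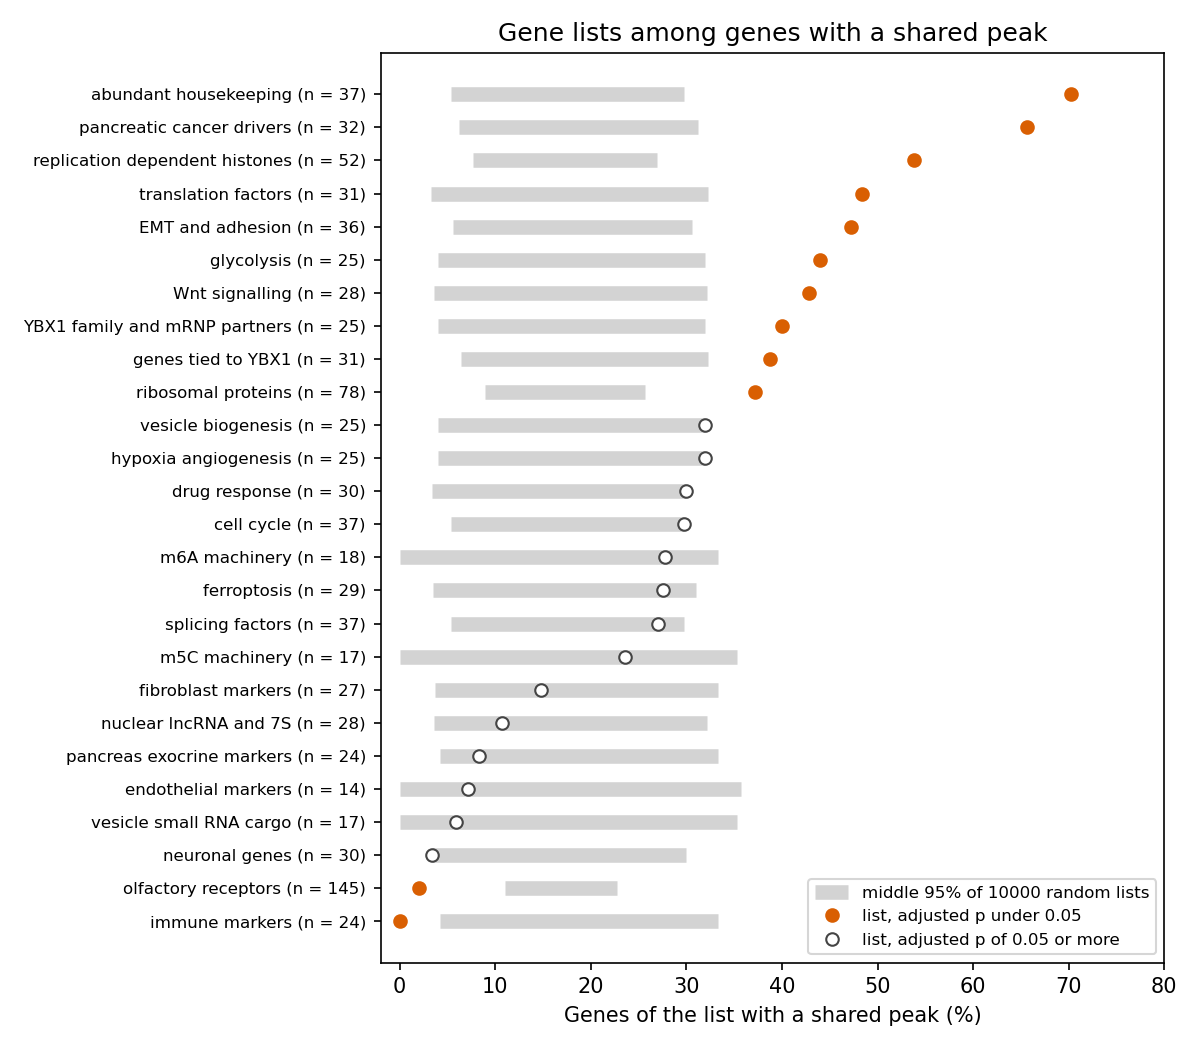
Percent of each gene list's members with a shared peak (x axis) for the 26 lists (y axis, with the number of members); grey bars span the middle 95% of 10000 random lists of the same size, and filled points have an adjusted permutation p under 0.05. Housekeeping genes are highest at 70.3% and immune markers lowest at 0%.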

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

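Thresholds beyond the planned ones, gene bounds and the added backgrounds were chosen after the data were seen. The overlap between replicates stayed above all random placements in each of the 6 settings where it was recomputed, but the shares of 31.6% and 34.7% became 22.2% and 49.1% at -log10 p of 5 or more and 8.54% and 82.7% at a score of 200 or more. No paired analysis was possible because each list is already 1 IP against its own input, and no values per sample remained to be modelled. The plan called for random lists matched on gene length, but with no hg19 lengths the unmatched lists are the reported test. The planned motif settings were not run. The causes of the changes were not tested, except where a setting removes peaks by construction. At -log10 p of 5 or more, replicate 2 kept 12498 peaks, the rho of folds was 0.468, the promoter and intergenic calls of replicate 2 ended (1.11 and 0.896), and the drug response, vesicle biogenesis and neuronal lists passed. The immune call ended there and in most other settings. At a fold of 4 or more the rho was 0.383, 1 list was below random lists and the YBX1 family call ended. With 50% overlap of both peaks the rho was 0.466, 1 list was below and the call of genes tied to YBX1 ended; with lists of equal length 1 list was below. With exon peaks only, 1914 genes held a shared peak, and 4 lists were above and 1 below random lists. The ribosomal and histone lists turned to 0.404 and 0 of the random mean. The exon class leaves out peaks within 2000 bp of a start, so shorter genes can hardly hold one. These values therefore decide nothing for such genes. Both YBX1 lists, glycolysis and translation factors no longer passed. With either list alone, genes numbered from 10863 to 11458, exon peaks made up 31.1% to 33.1%, and 13 to 17 lists were above; the exocrine list passed as fewer in both, and the YBX1 family call ended in replicate 1 (1.48). At a score of 200 or more, 15293 and 1570 peaks and 1112 genes remained, the rho was 0.516, and 5 lists were above and 0 below random lists, without the YBX1, adhesion, glycolysis and Wnt calls. The exon odds ratios turned to 0.791 and 0.520 there, and the intergenic ones to 1.46 and 1.5, and the replicate 2 intron odds ratio was 0.937 (adjusted exact p = 0.738). Counting genes by the bounds that hold the peak's middle left 1 list below and 13 above. It ended the histone call and added cell cycle, hypoxia, splicing and drug response. A peak that covers a short gene can have its middle outside it, so the histone change does not place those peaks in other genes. Against random lists matched on gene length 10 lists were above and the neuronal list passed as fewer (0.152 of the random mean). The span-matched background keeps only genes with a peak, such as 8 of the 145 olfactory genes, so it cannot show a lack of peaks; there 3 lists were above and 0 below, and the olfactory list stood at 1.19 by construction. Of the 80 named genes, 72 held a shared peak at -log10 p of 5 or more, 75 with 50% overlap, 43 with exon peaks only, 33 at a score of 200 or more and 68 by gene bounds. Smaller folds moved by over 1.5 times in 9, 6, 14, 14 and 9 genes in these settings. Library depths were not used; the median peak held 45 reads in replicate 1 and 15 in replicate 2.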

Other observations

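The tests of peaks grouped by p, of upstream peaks and of genomic DNA were chosen after their results were seen; the tests of equal-length lists and of neighbouring pseudogenes were written before. No biological explanation was tested for these patterns, since the design holds no untreated group.

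The peaks with the most reads often lay outside the listed genes. In replicate 1 the highest, with 616186 reads and a fold of 6.02, lay on chromosome 9 at 135894728 to 135896622, annotated to the promoter of SNORD141A and SNORD141B; another, with 152587 reads, lay upstream of STEAP1B on chromosome 7 at 22549879 to 22551683, where the neighbouring gene on that side is EEF1A1P6, a pseudogene of the elongation factor EEF1A1. These peaks were chosen after their values were seen. A candidate explanation is that reads across splice junctions aligned to processed pseudogenes, which lack introns. Among 1033 shared peaks outside every listed transcript, a pseudogene was the neighbour for 57 of the 104 with the most reads (54.8%) and 338 of the other 929 (36.4%), a ratio of 1.51 (95% interval 1.24 to 1.83; Fisher's exact p = 0.000401). That is barely past the bound of 1.5 set beforehand. The neighbour was the next gene in order on the peak's side, at any distance. Pseudogenes of every kind counted, such as RNU6-1082P and RNA5SP324, so the count is not of processed pseudogenes alone. The test was first run on 925 peaks without those in promoters, a departure from its stated form, and gave 1.49, under the bound, so the explanation stays a hypothesis, and 47 of the 104 peaks had no such neighbour.

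Most peaks of each list, as deposited, had no partner in the other, and peaks near the calling threshold may account for part of this. The share with a partner was 5.01 times as high in the 10% of replicate 1 peaks with the smallest p as in the 10% with the largest, and 2.91 times in replicate 2, short of the 3 set for both lists. Unequal thresholds of the lists were tested by cutting them to the same number of peaks, which raised the replicate 1 share by 1.14 percentage points. That test decides nothing: it removed 2177 peaks, and even if none of them had a partner the share would have risen by 2.70 points, so the bound of 10 points could not be reached. With a score of 200 or more in both lists, 82.7% of replicate 2 and 8.54% of replicate 1 peaks had a partner, and with 50 or more 49.1% and 22.2%, so unequal thresholds stay open.

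About 1 in 5 peaks was annotated upstream of a gene. Another gene's body under the peak may explain some of them. Of 5987 upstream peaks in replicate 1, 71.2% lay inside a listed transcript of another gene, against a mean of 60.1% and a highest value of 61.1% over 100 random placements in the same upstream windows. The ratio of 1.18 was above all placements but below the 1.3 set for the explanation, so it stays open.

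Reads from genomic DNA in the precipitate were tested with genes not thought to be transcribed in these cells. To argue against DNA, both lists had to stand under 0.5 of the background with an adjusted permutation p under 0.05. Against all genes the ratios were 0.123 and 0.198, with an adjusted permutation p of 0.000743 for olfactory and 0.103 for neuronal genes. Against random lists matched on gene length, added after that result was seen, they were 0.167 and 0.152 (adjusted permutation p = 0.000743 and 0.0328), which meets the bound. Shared peaks were thus rarer in these genes than in random lists matched on length. The counts cover only peaks called over input and found in both lists. Randomly placed peaks overlapped 1.40% of replicate 1 peaks, against 31.6% observed, so evenly spread DNA would hardly enter this set. The test therefore cannot decide whether the precipitate held such DNA. DNA from transcribed regions alone, or behind a smaller part of the peaks, was not tested. The neuronal value is near the bound and did not pass by transcript bounds (adjusted permutation p = 0.161).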
